A study of Mus musculus with 12 samples.

How the data were processed

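Poly(A) RNA of RAW264.7 cells was sequenced paired-end on an Illumina NovaSeq instrument, per the labels' protocols. The protocols name monoclonal lines with a stable shRNA against DCLK1 or a negative control shRNA, plated at 200000 cells per well, and 500 ng/ml LPS for 6 h. The 12 libraries form 4 groups of 3: control and shDCLK1 cells, each untreated and with LPS. The knockdown entry of the control samples is "none", while the protocol gives them a negative control shRNA; they are called control cells. Groups follow the labels, and the strain entry was not used.

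The values are FPKM per gene with 2 decimals, as deposited by the authors in 1 table of 18190 genes by 12 libraries. The submitters' processing notes name Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0 and the builds mm8 and mm9, with no role or order for any of them, so no coordinates are given. Neither the annotation, a filter nor the use of strand is stated in the sources used here. All 12 columns of values were mapped to samples. A column without a name, with 18 entries, was not used. Symbols turned into dates by a spreadsheet were restored for 27 genes from their Entrez Gene IDs. Of the IDs, 18142 were found in a RefSeq gene table of GRCm38.p6, used for names alone, and 17379 had the same symbol there. Near-identical genes (Bcl2a1a, Bcl2a1b and Bcl2a1d, Lyz1 and Lyz2, Apol9a and Apol9b, Ifit3 and Ifit3b, Oas1a and Oas1g) are uncertain, since how shared reads were divided is not stated.

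Depth was read from the values. The FPKM of short RNA genes are whole multiples of what 1 fragment is worth, and the steps of 127 such genes gave each library's relative depth, with a residual SD of 0.217%. Only genes whose values in all libraries lay close to whole multiples of their lowest value were used. This choice favours equal depths, so a larger difference could be missed. Counts and intervals for counting error were not available.

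From here on, values were computed with R 4.3.3 and limma 3.58.1, and figures drawn with Python 3.11.15 and matplotlib 3.10.9. Genes at 1 FPKM or more in at least 3 libraries were kept (11052), and log2(FPKM + 1) was fitted with limma with a mean per group over all 12 libraries and moderated with a mean trend. The 5 comparisons were LPS against untreated in each line, shDCLK1 against control cells without and with LPS, and the interaction. P-values are two-sided, adjusted by the Benjamini-Hochberg method within a comparison, and a gene was called at an adjusted p under 0.05. The median SE of a log2 change was 0.0534, and 0.0755 for the interaction. The values were used without further scaling.

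Gene lists were tested with limma's camera, which asks whether the mean test statistic of a list's genes differs from that of other genes. It was run with a preset correlation of 0.01 and again with an estimated one. Its p was adjusted over the lists with at least 3 measured members within a comparison. There were 30 lists. The 6 primary ones hold NF-κB subunits and feedback inhibitors, IKK and TLR4 signalling components, inflammatory cytokines, chemokines, type I interferon response genes, and inflammatory enzymes and mediators. The others hold immediate-early and AP-1 factors, inflammasome, MHC and antigen presentation, macrophage identity, alternative activation, cell cycle, cholesterol synthesis, lipid efflux, glycolysis, oxidative phosphorylation, stress response, lysosome, osteoclast, dendritic cell, adipocyte, Y-linked, ribosomal protein and histone genes. Lists of fibroblast, epithelial, lymphocyte, neutrophil and mast cell, doublecortin and mitochondrially encoded genes had too few measured members to test. The list named for NF-κB subunits and feedback inhibitors also holds genes that are neither, such as Cd40, Icam1, Sqstm1 and the Bcl2a1 copies. Counts of members are given over all genes tested and adjusted over the list alone.

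Genes were named by a rule set before the data were examined, like the lists, their tests and all alternatives but 1. The tests of explanations other than chance were chosen after the results were seen. It names Dclk1, Dclk2, Dclk3, Dcx and Ikbkb. In each comparison it names the 6 genes most above and most below 0 among called genes with no overlap between the groups of 3 (asked of no gene in the interaction; chance gives 10% of genes) and a mean of 5 FPKM or more, without predicted models. It names the 3 called members with the largest change of each primary list, and the 2 of each other list that camera called. A few of the genes it names are left out of the text. Genes raised or lowered by LPS were chosen on the average response of both lines (called, and a mean log2 change of at least 1 or at most -1), whose error is independent of that of the interaction. Folds are ratios of mean FPKM.

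The procedure was tested on simulated data with known changes in 50 genes at each size, over 11052 genes. For LPS in control cells 72%, 100% and 98% of changes of 0.25, 0.5 and 1 log2 units were recovered. Of all the genes outside the 200 changed ones, 4 were called. For shDCLK1 against control cells without LPS 72%, 98% and 100% were recovered, with 10 unchanged genes called. For the interaction it was 30%, 80% and 100%, with 8 unchanged genes called. Genes low in untreated control cells were given no change, so recovery of low genes was not tested. The noise was normal, independent between genes and of the fitted spread, as the test assumes, so few false calls were close to assured. Far more genes than 200 were called in the data, so these shares need not hold there.

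The alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-of-ratios scaling, rescaling each library to the same sum (TPM), quantile normalization, no mean trend, weights per library, the replicate number as a block, fits on the 6 libraries of a comparison, each library left out in turn, and camera with an estimated correlation. Leaving out the untreated libraries numbered 3 of both lines was added after the data were seen. Label swaps within the groups compared were counted, 10 splits for a comparison and 100 drawn for the interaction.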

Results

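RNA sequencing was done on RAW264.7 cells, a mouse macrophage line, in which 1 clonal line carried an shRNA against Dclk1 (doublecortin-like kinase 1) and the other a negative control shRNA. Each line was sampled untreated and after 6 h with 500 ng/ml lipopolysaccharide (LPS, the bacterial cell wall component sensed by TLR4), with 3 libraries in each of the 4 groups. Values are FPKM as deposited, and levels are given as mean ± SD (n = 3). Changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Whether replicate libraries came from separate cultures is not stated, so p measures the spread between these libraries, which can be technical. The FPKM of a library summed to between 457695 and 495373, and 10119 to 10619 genes reached 1 FPKM. Read totals were not given. The smallest FPKM steps of 127 short RNA genes, chosen in a way that favours equal depths, put the relative depth of the libraries between 0.974 and 1.01. Libraries of the same group correlated at r = 0.993 to 0.996 over the tested genes. Those that differed in line alone correlated at 0.977 to 0.986, and those that differed in treatment alone at 0.806 to 0.866. The 10 most abundant genes took 7.07% ± 0.103 of the FPKM sum in untreated control cells and 6.59% ± 0.0885 in untreated shDCLK1 cells. With LPS they took 10.97% ± 0.211 in control cells and 8.91% ± 0.0298 in shDCLK1 cells.

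Dclk1, the target of the shRNA, was at the floor of the measurement in every library. Its value was 0.01 FPKM in the first and second untreated control libraries and in the first untreated shDCLK1 library, and it was listed at 0 in the others. The knockdown could therefore not be checked in these values, and the groups rest on their labels. Its relatives were as low, with at most 0.04 FPKM for Dclk2 and 0.06 FPKM for Dcx in any library, and Dclk3 was not analysed here. Ikbkb (Entrez Gene ID 16150) encodes IKKβ, the kinase named with DCLK1 in the study's title. It was at 24.7 ± 1.01 FPKM in untreated control cells and 22.6 ± 0.438 in untreated shDCLK1 cells. With LPS it was at 19.2 ± 0.460 in control cells and 19.5 ± 0.495 in shDCLK1 cells. The difference between untreated lines was -0.12 log2 units (SE 0.0359, adjusted p = 0.0150). That call was lost without the second untreated control library (adjusted p = 0.0692), without the second untreated shDCLK1 library (adjusted p = 0.0545) and after rescaling to equal sums (adjusted p = 0.0502). With LPS the lines differed by 0.02 log2 units (SE 0.0359, adjusted p = 0.705). Markers of other cell types differed in level. The highest epithelial marker was Krt8 at 0.4 FPKM and the highest lymphocyte marker Pax5 at 1.3 FPKM, while Vim, of the fibroblast markers, reached 382 FPKM and Cxcr2, of the neutrophil and mast cell markers, 22.2 FPKM. The 3 measured adipocyte markers and the 4 measured Y-linked genes were called as a list in no comparison. Their lowest camera adjusted p were 0.127 and 0.0693, and the mitochondrially encoded genes were not analysed here.

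The first comparison asked how control cells responded to LPS. Control cells raised inflammatory and interferon genes, some of them from near silence, and shut down proliferation genes. The chemokine Ccl5 went from 4.96 ± 3.41 to 8612 ± 525 FPKM, a rise of 10.64 log2 units. The cytokines Il1b and Il6 went from 0.347 ± 0.431 to 1156 ± 34.1 FPKM and from 0.0167 ± 0.0289 to 346 ± 4.43 FPKM, rises of 9.79 and 8.42 log2 units. Acod1, which makes itaconate, went from 2.20 ± 1.12 to 2572 ± 53.8 FPKM, and the cytokine Il1a and chemokine Ccl22 rose by 8.89 and 8.57 log2 units. Tk1 (thymidine kinase) fell from 81.8 ± 2.12 to 1.39 ± 0.284 FPKM and Plau (urokinase) from 189 ± 3.62 to 5.03 ± 0.293 FPKM. Ccna2 (cyclin A2), Birc5 (survivin), Kbtbd11 and E2f8 were the next lowest.

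All 47 measured members of the type I interferon list rose in control cells (47 adjusted over the list alone), with a median rise of 4.34 log2 units (camera adjusted p = 6.64e-35). Rsad2 (viperin) rose by 8.08 log2 units, Ifit3 by 7.35 and Gbp3 by 6.67. Of 23 inflammatory cytokines 22 rose and 1 fell (23 adjusted over the list alone, camera adjusted p = 8.97e-15). Of 18 chemokines 16 rose and 1 fell (17 adjusted over the list alone, camera adjusted p = 2.00e-10), and Cxcl2 reached 695 ± 10.4 FPKM. The list of NF-κB subunits and feedback inhibitors rose in 22 of 25 members and fell in 2 (24 adjusted over the list alone, median 2.40, camera adjusted p = 9.29e-14). Its largest rises were in Nfkbiz, Cd40 and Bcl2a1a, whose reads may be shared with its copies Bcl2a1b and Bcl2a1d. Inflammatory enzymes and mediators rose in 24 of 26 and fell in 2 (26 adjusted over the list alone, camera adjusted p = 2.71e-14). Ptgs2 (cyclooxygenase-2) went from 2.20 ± 0.215 to 801 ± 11.5 FPKM and Hdc (histidine decarboxylase) reached 95.9 ± 2.68. Immediate-early and AP-1 factors rose in 21 of 29 and fell in 6 (27 adjusted over the list alone, camera adjusted p = 3.27e-09). Dusp5 and Dusp1, phosphatases that act on MAP kinases, rose by 5.45 and 4.75 log2 units. MHC and antigen presentation genes rose in 18 of 19 and fell in 1 (19 adjusted over the list alone, camera adjusted p = 1.45e-11), led by Cd274 (PD-L1) and Tap1.

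All 40 cell cycle genes fell in control cells (40 adjusted over the list alone), with a median log2 change of -3.55 (camera adjusted p = 7.05e-11). Macrophage surface and identity genes split, with 16 of 27 up and 8 down (24 adjusted over the list alone, camera adjusted p = 2.95e-04). The scavenger receptor Msr1 rose by 4.40 log2 units and Axl by 3.89. Components of the IKK and TLR4 pathway split too, with 13 up and 11 down of 29 (24 adjusted over the list alone). Ikbke and the LPS co-receptor Cd14 rose by 4.42 and 4.19 log2 units and Map3k8 by 2.03. The call of this list (camera adjusted p = 0.0149) was lost at adjusted p = 0.0533 with an estimated correlation. Oxidative phosphorylation genes fell in 27 of 31 members and rose in 1 (28 adjusted over the list alone, camera adjusted p = 0.0231). Atp5c1 went from 184 ± 5.97 to 93.9 ± 1.84 FPKM and Cyc1 from 157 ± 2.12 to 83.0 ± 1.05. That call was lost at adjusted p = 0.533 with an estimated correlation, and at 0.530 after median-of-ratios scaling, where the list's median was -0.05. Alternative activation markers had 5 up and 3 down of 9 (8 adjusted over the list alone), led by Ccl22 and Ccl17. Their call was lost at adjusted p = 0.0706 with an estimated correlation and at 0.0885 after scaling. Dendritic cell markers had 4 up and 2 down of 6 (6 adjusted over the list alone), with Ccr7 at 7.87 ± 0.643 FPKM and Xcr1 at 3.10 ± 0.127 with LPS. Their call was lost at adjusted p = 0.0772 with an estimated correlation and at 0.167 after scaling. Ribosomal protein genes were not called (camera adjusted p = 0.392), but were after scaling (adjusted p = 5.94e-05), which turned their median from -0.08 to 0.35.

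In the limma fit 9604 of 11052 genes passed an adjusted p of 0.05 in control cells, 2741 higher and 6863 lower with LPS. By at least 1 log2 unit 917 rose and 2379 fell. The median change of all genes was -0.38, so that scaling decides the direction of small changes. The split was 4708 higher and 4728 lower after median-of-ratios scaling and 4376 higher and 4960 lower after quantile normalization.

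The second comparison put the same question to shDCLK1 cells. They turned on the same classes of gene and shut down the same proliferation genes, by smaller steps for many of them. Il1b reached 1187 ± 18.5 FPKM from 1.06 ± 0.410 and Il1a 786 ± 22.5 from 0.560 ± 0.349. Csf3 (the growth factor G-CSF) reached 283 ± 38.6 FPKM from 0.173 ± 0.101, and Acod1 2076 ± 8.82 from 8.38 ± 0.994. Ccl5 reached 4265 ± 153 FPKM and Ccl22 326 ± 16.8, rises of 8.59 and 8.02 log2 units. The deepest fall was in Cd24a, a surface glycoprotein, from 49.4 ± 1.46 to 0.477 ± 0.0208 FPKM, and Tk1, Fam64a, Rasgrp3 and Ccna2 were among the next.

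All 47 interferon genes rose in shDCLK1 cells as well (47 adjusted over the list alone), by a median of 2.58 log2 units (camera adjusted p = 1.92e-31). Rsad2 rose by 5.81 log2 units, Gbp5 by 5.63 and Gbp2 by 5.35. Cytokines rose in 22 of 23 members and fell in 1 (23 adjusted over the list alone, camera adjusted p = 3.07e-15). Chemokines rose in 17 of 18 and fell in 1 (18 adjusted over the list alone, camera adjusted p = 1.22e-12), with Cxcl2 at 776 ± 21.5 FPKM. NF-κB subunits and feedback inhibitors rose in 21 of 25 and fell in 2 (23 adjusted over the list alone, median 1.91, camera adjusted p = 1.88e-13), led by Bcl2a1a, Nfkbiz and Cd40. Inflammatory enzymes rose in 24 of 26 and fell in 2 (26 adjusted over the list alone, camera adjusted p = 2.76e-15). Ptgs2 reached 459 ± 7.68 FPKM and Nos2 (inducible nitric oxide synthase) 58.9 ± 10.8. Immediate-early genes rose in 20 of 29 and fell in 7 (27 adjusted over the list alone, camera adjusted p = 1.10e-07), led by Dusp5 and Ier3. MHC and antigen presentation genes rose in 15 of 19 and fell in 4 (19 adjusted over the list alone, camera adjusted p = 2.66e-07), led by Cd274 and Cd80. Macrophage identity genes rose in 16 of 27 and fell in 10 (26 adjusted over the list alone, camera adjusted p = 0.00245). The largest changes in that list were falls, of the transcription factor Cebpa from 15.6 ± 1.17 to 0.957 ± 0.132 FPKM and of Sirpa from 60.8 ± 1.10 to 9.01 ± 0.755 FPKM. Alternative activation markers rose in 6 of 9 and fell in 2 (8 adjusted over the list alone, camera adjusted p = 0.00731), led by Ccl22 and the transglutaminase Tgm2.

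All 40 cell cycle genes fell in shDCLK1 cells (40 adjusted over the list alone, camera adjusted p = 6.64e-11), with a median log2 change of -2.53. Cholesterol synthesis genes fell in 20 of 23 and rose in 2 (22 adjusted over the list alone, camera adjusted p = 0.00463, and adjusted p = 0.159 with an estimated correlation). Dhcr7 went from 21.8 ± 1.12 to 3.15 ± 0.267 FPKM. Osteoclast markers rose in 7 of 10 and fell in 3 (10 adjusted over the list alone, camera adjusted p = 0.00567), led by Src and Acp5 (tartrate-resistant acid phosphatase). Inflammasome genes rose in 7 of 12 and fell in 4 (11 adjusted over the list alone, camera adjusted p = 0.0192), led by Nlrp3 and Casp4. Both calls were lost at adjusted p = 0.0613 with an estimated correlation, and that of the inflammasome list also after scaling (adjusted p = 0.125). Dendritic cell markers had 4 up and 2 down of 6 (6 adjusted over the list alone), with the largest changes in Ccr7 and Siglech. They were called at camera adjusted p = 0.0380, and lost at adjusted p = 0.0902 with an estimated correlation and at 0.215 after scaling. IKK and TLR4 components rose in 12 and fell in 13 of 29 (25 adjusted over the list alone, camera adjusted p = 0.0181, and adjusted p = 0.0613 with an estimated correlation). Ikbke rose by 4.34 log2 units and Cd14 by 3.97, and the adaptor Ticam2 fell from 11.5 ± 0.405 to 2.62 ± 0.285 FPKM. Ribosomal protein genes rose in 9 of 30 and fell in 5 (13 adjusted over the list alone, camera adjusted p = 0.0114, and adjusted p = 0.526 with an estimated correlation). Rps23 and Rplp1 rose by 0.27 and 0.24 log2 units as deposited. After quantile normalization Rps23 was not called (adjusted p = 0.152) and the change of Rplp1 was -0.56.

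In shDCLK1 cells 9349 genes passed the threshold in limma, 2747 higher and 6602 lower with LPS, and 762 rose and 1713 fell by at least 1 log2 unit. The median change of all genes was -0.29. The split was 4548 higher and 4562 lower after median-of-ratios scaling and 4240 higher and 4815 lower after quantile normalization. The change of Ikbkb with LPS was -0.34 log2 units in control cells (adjusted p = 1.03e-06) and -0.20 in shDCLK1 cells (adjusted p = 1.56e-04) as deposited. Scaling turned these around: they were 0.06 (adjusted p = 0.109) and 0.11 (adjusted p = 0.0101) after median-of-ratios scaling. Quantile normalization gave -0.02 (adjusted p = 0.674) and 0.06 (adjusted p = 0.116).

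**Figure D1:**
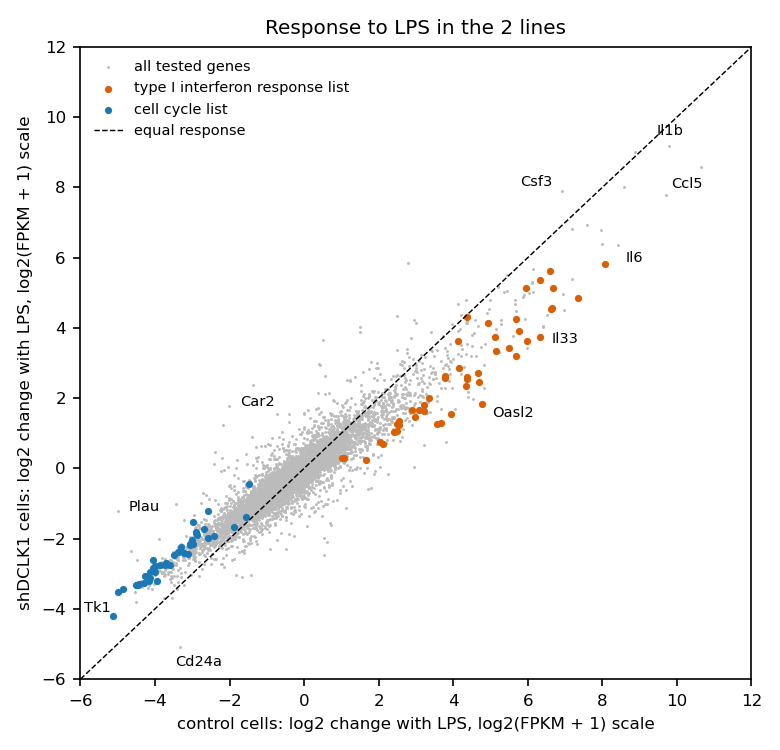
Log2 change with LPS (log2(FPKM + 1) scale) of each of 11052 tested genes in control cells (x axis) and shDCLK1 cells (y axis), 3 libraries per group, with the interferon and cell cycle lists in colour and the dashed line marking equal change. The 2 responses correlated at r = 0.936 over genes, and most interferon genes lie below the line and most cell cycle genes above it.

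The third comparison asked how shDCLK1 cells differed from control cells before any LPS. Untreated shDCLK1 cells held a raised interferon-response program and more of several macrophage and lysosome transcripts. Oasl2 was at 62.7 ± 1.67 FPKM against 7.20 ± 0.255 in control cells, and Trim30a at 42.8 ± 1.35 against 4.99 ± 0.113. Apol9b and Apol9a, near-identical copies whose reads may be divided uncertainly, were 11.5-fold and 8.77-fold higher. Lyz2 (lysozyme), a close copy of Lyz1, was at 642 ± 9.35 against 97.3 ± 3.61 FPKM and the inhibitory receptor Lilrb4a at 89.9 ± 3.06 against 13.6 ± 1.01. In the other direction Id3, an inhibitor of helix-loop-helix transcription factors, was at 1.95 ± 0.0208 against 27.8 ± 1.32 FPKM. Car2 (carbonic anhydrase 2) was at 41.3 ± 0.633 against 135 ± 2.45.

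All 47 interferon genes were higher in untreated shDCLK1 cells (47 adjusted over the list alone), by a median of 1.42 log2 units (camera adjusted p = 3.98e-47, and adjusted p = 0.00137 with an estimated correlation). Among them the nucleic acid sensor Zbp1 was at 18.6 ± 0.825 against 2.35 ± 0.412 FPKM. Chemokines were higher in 10 of 18 and lower in 0 (10 adjusted over the list alone, camera adjusted p = 9.46e-06). Ccl4 was at 97.0 ± 2.72 against 31.4 ± 2.81 FPKM, Cxcl10 at 22.1 ± 0.434 against 6.89 ± 0.891 and Ccl9 at 94.6 ± 1.99 against 34.4 ± 0.548. Cytokines were higher in 9 of 23 and lower in 1 (10 adjusted over the list alone, camera adjusted p = 0.00188), with Csf1, Tnfsf9 and Il18 higher by 0.93, 0.75 and 0.71 log2 units. Macrophage identity genes were higher in 21 of 27 and lower in 1 (23 adjusted over the list alone, camera adjusted p = 8.34e-11). Beside Lyz2, Msr1 was at 29.8 ± 0.952 against 6.00 ± 0.553 FPKM. MHC and antigen presentation genes were higher in 15 of 19 and lower in 2 (17 adjusted over the list alone, camera adjusted p = 6.86e-08), with Tap1 and H2-Aa higher by 1.01 and 0.99 log2 units. Immediate-early factors were higher in 18 of 29 and lower in 3 (24 adjusted over the list alone, camera adjusted p = 3.08e-05), led by Myc and Klf4. Inflammatory enzymes and mediators were higher in 10 of 26 and lower in 1 (11 adjusted over the list alone, camera adjusted p = 8.58e-04, and adjusted p = 0.0960 with an estimated correlation). Acod1, the protease inhibitor Slpi and the lectin Clec4e were higher by 1.60, 1.41 and 1.17 log2 units. Traces of the genes that LPS raised most differed between the untreated control libraries. In libraries 1, 2 and 3, Il1b was at 0.04, 0.16 and 0.84 FPKM, Ccl5 at 2.73, 3.27 and 8.88 and Acod1 at 1.66, 1.46 and 3.49. The third untreated shDCLK1 library was the highest of its group for these genes too. There Il1b was at 0.83, 0.81 and 1.53 FPKM, Ccl5 at 9.41, 9.16 and 11.75 and Acod1 at 8.19, 7.5 and 9.46 in libraries 1, 2 and 3.

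Lysosome genes were higher in 22 of 25 and lower in 1 (23 adjusted over the list alone, camera adjusted p = 1.57e-10, and adjusted p = 0.0976 with an estimated correlation). Grn (progranulin) was at 309 ± 13.2 against 121 ± 2.74 FPKM and the protease Ctsb was 1.73-fold higher. Cell cycle genes were lower in 30 of 40 and higher in 2 (35 adjusted over the list alone, camera adjusted p = 1.41e-06, and adjusted p = 0.0721 with an estimated correlation). Their median was -0.21, and Cenpf and Cenpe differed most. Ribosomal protein genes were lower in 24 of 30 (25 adjusted over the list alone, median -0.17, camera adjusted p = 1.76e-06, and adjusted p = 0.253 with an estimated correlation). Rpsa was among those that differed most. Glycolysis genes were lower in 17 of 23 and higher in 3 (20 adjusted over the list alone, camera adjusted p = 3.68e-04, and adjusted p = 0.136 with an estimated correlation). The difference was -0.59 log2 units for Pdk1 and 0.91 for the hexokinase Hk3. Genes of the unfolded protein and integrated stress responses were higher in 13 of 25 and lower in 4 (20 adjusted over the list alone, camera adjusted p = 0.0112, and adjusted p = 0.129 with an estimated correlation), led by Atf5 and Ddit3. Lipid efflux genes were higher in 7 of 12 and lower in 1 (8 adjusted over the list alone, camera adjusted p = 0.0102, and adjusted p = 0.0972 with an estimated correlation), led by Abcg1 and Pltp. Cholesterol synthesis genes were higher in 8 of 23 and lower in 2 (10 adjusted over the list alone, camera adjusted p = 0.0281, and adjusted p = 0.253 with an estimated correlation), led by Idi1 and Insig1. Osteoclast markers were higher in 6 of 10 and lower in 1 (8 adjusted over the list alone, camera adjusted p = 0.0339, and adjusted p = 0.151 with an estimated correlation), with Car2 lower and Atp6v0d2 higher. The NF-κB and the IKK and TLR4 lists were not called (camera adjusted p = 0.133 and 0.277). In the former, 8 of 25 members were higher and 3 lower (11 adjusted over the list alone), led by Sqstm1, Cd40 and Traf1. In the latter 11 of 29 were higher and 5 lower (17 adjusted over the list alone), led by Irak3, Tlr4 and Ticam2. Tlr4, the LPS receptor, was at 8.13 ± 0.387 against 4.89 ± 0.0611 FPKM.

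In limma 4976 genes differed without LPS, 2364 higher and 2612 lower in shDCLK1 cells, but 186 were higher and 21 lower by at least 1 log2 unit. The split was 2527 higher and 2161 lower after rescaling to equal sums, and 2189 higher and 2993 lower after quantile normalization. Of the 6 deepest differences below 0, 4 were of short RNA genes that rest on few fragments. In the untreated control libraries Snord42b was at 5.71, 11.6 and 8.49 FPKM and Snord99 at 13.6, 5.52 and 5.37 FPKM. Both were listed at 0 in the untreated shDCLK1 libraries, and 1 fragment was worth 2.83 and 2.69 FPKM. The difference was -2.21 log2 units for Mir5107 (adjusted p = 0.00232) and -1.37 for Mir5125 (adjusted p = 0.0282). The call of Mir5125 was lost without the first or second untreated control library (adjusted p = 0.0707 and 0.0727), without the third untreated shDCLK1 library (-0.81, adjusted p = 0.114) and with no filter on low genes (adjusted p = 0.0694).

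The fourth comparison asked how the lines differed after LPS. With LPS, shDCLK1 cells held less of several NF-κB feedback and cytokine transcripts and more of proliferation, osteoclast-type and some chemokine and protease transcripts. Il6 was at 106 ± 4.88 FPKM against 346 ± 4.43 in control cells, 3.27-fold lower, and the alarmin Il33 was at 15.7 ± 2.01 against 85.8 ± 2.36, 5.45-fold lower. Plau was 15.8-fold higher, at 79.2 ± 7.72 against 5.03 ± 0.293 FPKM. The monocyte chemokine Ccl2 was 8.77-fold higher, at 66.0 ± 4.30 against 7.52 ± 1.35, and the gelatinase Mmp9 8.05-fold higher, at 17.8 ± 3.09 against 2.22 ± 0.351. Mustn1, the actin-severing protein Scin and the pyrophosphate transporter Ank were the other genes of the 6 most above control cells. Cp (ceruloplasmin), Avil, Rnd1 and Ddit4 were, with Il6 and Il33, the 6 most below. Tnf, chosen after its values were seen, was at 501.4 FPKM against 531.5 in control cells with LPS and was not called (adjusted p = 0.116).

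Of 25 NF-κB subunits and feedback inhibitors 17 were lower and 3 higher in shDCLK1 cells with LPS (20 adjusted over the list alone, median -0.33). The list was called at camera adjusted p = 1.00e-08, and at adjusted p = 0.00318 with an estimated correlation. Bcl3 was at 45.2 ± 4.35 against 114 ± 2.84 FPKM, the deubiquitinase Tnfaip3 (A20) at 42.5 ± 1.51 against 104 ± 1.39 and Tnip3 at 50.7 ± 1.51 against 90.7 ± 2.68. Cytokines were lower in 10 of 23 and higher in 6 (16 adjusted over the list alone, camera adjusted p = 0.00281), a call lost after quantile normalization (adjusted p = 0.0744). Csf3 was among the higher, at 283 ± 38.6 against 125 ± 3.34 FPKM. Stress response genes were lower in 17 of 25 and higher in 3 (20 adjusted over the list alone, camera adjusted p = 1.97e-08). The differences of Trib3 and Atf5 were -1.09 and -0.83 log2 units. Chemokines moved both ways, with 9 of 18 higher and 6 lower (15 adjusted over the list alone), and were not called (camera adjusted p = 0.753). Ccl7 and Ccl24 were higher beside Ccl2, at 3.44 ± 0.806 and 1.79 ± 0.136 FPKM, 11.5-fold and 12.8-fold above control cells. These folds rest on control levels near the floor. The control libraries with LPS were at 0.24, 0.36 and 0.3 FPKM for Ccl7 and at 0.13, 0.12 and 0.17 for Ccl24. Inflammatory enzymes and mediators were higher in 9 of 26 and lower in 12 (22 adjusted over the list alone) and were not called (camera adjusted p = 0.0713), with Serpinb2 higher beside Plau and Mmp9. The sign of their median (-0.13) and mean (0.14) differed, and they were called without the third untreated control library (adjusted p = 0.0469) or with genes at 5 FPKM or more alone (adjusted p = 0.0156).

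Interferon genes stood close to equal in the lines after LPS, with 13 of 47 higher and 20 lower in shDCLK1 cells (35 adjusted over the list alone, median -0.02). Their call (camera adjusted p = 0.0384) was lost at adjusted p = 0.328 with an estimated correlation. It was also lost without the first shDCLK1 library with LPS (adjusted p = 0.0680), after quantile normalization (adjusted p = 0.721) and with no filter on low genes (adjusted p = 0.0601). The largest differences were -0.66 for Ifi205, 0.52 for Ifit3b, which shares sequence with Ifit3, and -0.51 for Gbp5. IKK and TLR4 components were not called (camera adjusted p = 0.125) as deposited and were called after median-of-ratios scaling (adjusted p = 0.0401). Of 29 members 5 were higher and 7 lower (12 adjusted over the list alone), with differences of 0.69 for Tlr4, -0.68 for Map3k8 and -0.32 for Ticam2. Inflammasome genes were higher in 7 of 12 and lower in 1 (8 adjusted over the list alone) and alternative activation markers higher in 6 of 9 and lower in 2 (8 adjusted over the list alone). Neither list was called (camera adjusted p = 0.200 and 0.221).

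Cell cycle genes were higher in 38 of 40 in shDCLK1 cells with LPS (38 adjusted over the list alone, median 0.80). The list was called at camera adjusted p = 3.49e-18, and at adjusted p = 0.0111 with an estimated correlation. Ccnd1 (cyclin D1) was at 193 ± 11.6 against 75.3 ± 0.651 FPKM and Rrm2, a subunit of ribonucleotide reductase, at 6.10 ± 0.393 against 1.88 ± 0.130. Osteoclast markers were higher in 7 of 10 and lower in 0 (7 adjusted over the list alone, camera adjusted p = 1.53e-04). The transcription factor Nfatc1 was at 50.7 ± 1.29 against 10.9 ± 0.470 FPKM and Car2 at 143 ± 2.78 against 32.8 ± 0.919. Macrophage identity genes were higher in 15 of 27 and lower in 6 (21 adjusted over the list alone, camera adjusted p = 0.0446, and adjusted p = 0.169 with an estimated correlation). Lyz2 was at 966 ± 43.0 against 206 ± 4.87 FPKM and the growth factor receptor Csf1r at 64.9 ± 1.05 against 15.8 ± 0.386. Lysosome genes were higher in 22 of 25 and lower in 1 (23 adjusted over the list alone, camera adjusted p = 1.07e-05, and adjusted p = 0.264 with an estimated correlation), led by Gusb and Ctsb. MHC and antigen presentation genes were higher in 5 of 19 and lower in 6 (11 adjusted over the list alone, camera adjusted p = 0.0384, and adjusted p = 0.264 with an estimated correlation). The differences of the class II chains H2-Ab1 and H2-Aa were -1.47 and -1.35 log2 units.

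A further group of list calls with LPS was lost with an estimated correlation. Immediate-early factors were higher in 11 and lower in 12 of 29 (23 adjusted over the list alone, and adjusted p = 0.264 with an estimated correlation), with Dusp6 higher and Dusp1 lower. Glycolysis genes were higher in 6 and lower in 9 of 23 (16 adjusted over the list alone, and adjusted p = 0.266 with an estimated correlation), with Pfkfb3 at 16.9 ± 2.41 against 56.0 ± 0.696 FPKM and Hk3 higher. Oxidative phosphorylation genes were higher in 18 of 31 and lower in 0 (19 adjusted over the list alone, and adjusted p = 0.328 with an estimated correlation), led by Sdhb and Atp5c1. Ribosomal protein genes were lower in 8 of 30 and higher in 0 (2 adjusted over the list alone, and adjusted p = 0.328 with an estimated correlation), led by Rpl3 and Rpl5. Cholesterol synthesis genes were lower in 6 and higher in 2 of 23 (8 adjusted over the list alone, and adjusted p = 0.266 with an estimated correlation), with Srebf2 and Hmgcs1 lower. Lipid efflux genes were higher in 7 and lower in 2 of 12 (9 adjusted over the list alone, and adjusted p = 0.257 with an estimated correlation), with Abcg1 and Lpl higher. Replication-dependent histones were higher in 4 of 5 (4 adjusted over the list alone, and adjusted p = 0.264 with an estimated correlation), led by Hist1h1c and Hist1h2bc. Dendritic cell markers were lower in 3 and higher in 1 of 6 (5 adjusted over the list alone, and adjusted p = 0.173 with an estimated correlation), with Ccr7 lower and Itgax higher. Median-of-ratios scaling ended the calls of immediate-early factors, oxidative phosphorylation genes (both adjusted p = 0.190) and dendritic cell markers (adjusted p = 0.123).

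In limma 5371 genes differed with LPS, 3788 higher and 1583 lower in shDCLK1 cells, and 153 were higher and 46 lower by at least 1 log2 unit. The split was 2573 higher and 2891 lower after median-of-ratios scaling, which moved the median of all genes from 0.07 to -0.01. It was 2356 higher and 2744 lower after quantile normalization.

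**Figure D2:**
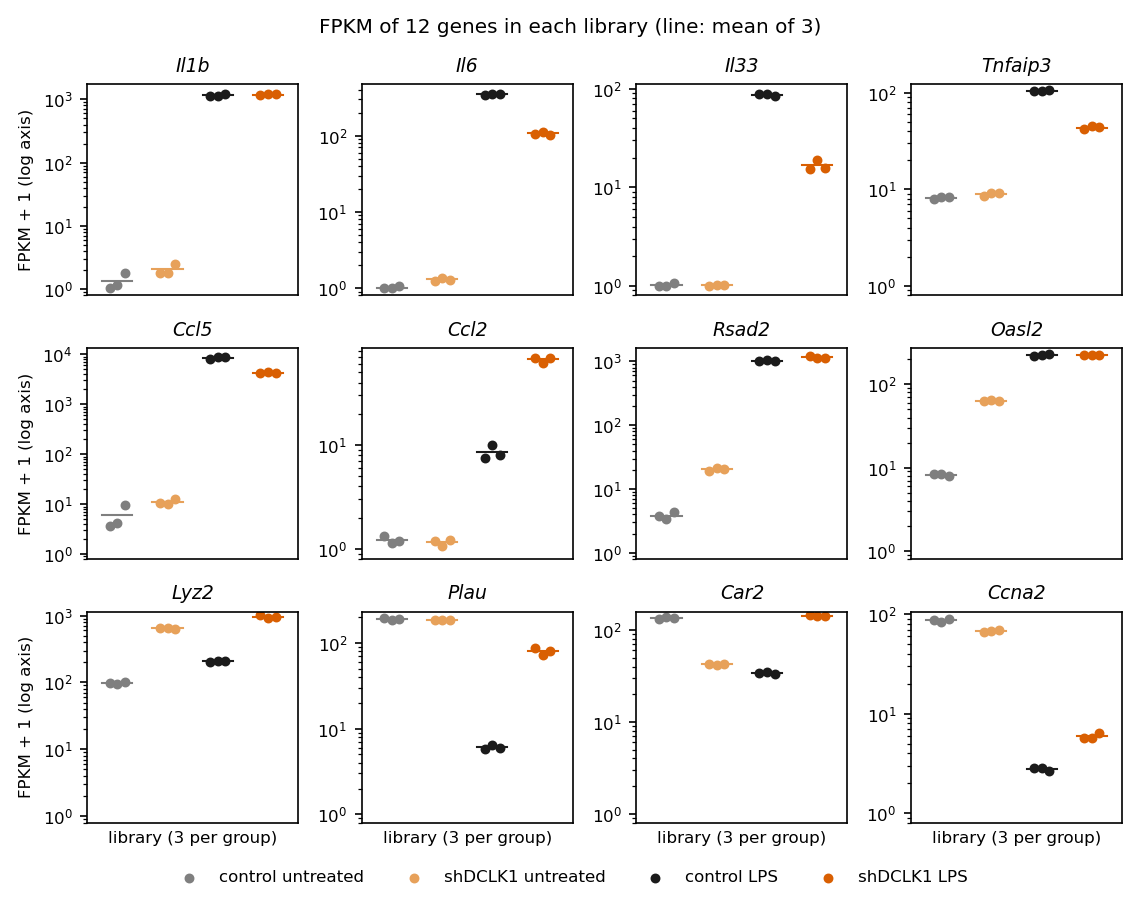
FPKM + 1 on a log axis of 12 genes in each of the 12 libraries, 3 points per group, with a line at the mean. The points of Il6 and Il33 with LPS lie lower in shDCLK1 than in control cells, those of Plau and Ccl2 higher, and those of Oasl2 and Lyz2 are higher in shDCLK1 cells already without LPS.

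The last comparison asked whether the response to LPS itself differed between the lines, as the interaction of line and treatment. The rises were smaller in shDCLK1 cells for most interferon and many inflammatory genes, and the falls were smaller for most proliferation genes. The most positive interactions were those of Plau (3.78), Car2 (3.77), Id3 (3.15), Ccl2 (3.06) and the short RNA genes Snord42b (3.74) and Snord99 (3.44). The most negative were those of the membrane proteins Ms4a6d (-3.05) and Ms4a6c (-2.91), Oasl2 (-2.94), Zbp1 (-2.58), Lilrb4a (-2.55) and Ifi44l (-2.55). LPS raised 822 genes by at least 1 log2 unit on the average of both lines, with a median rise of 1.93 log2 units in control cells and 1.56 in shDCLK1 cells. Their median interaction was -0.40 (camera p = 2.99e-32, and p = 6.88e-08 with an estimated correlation), and 494 had a smaller and 106 a larger rise in shDCLK1 cells. Of the 822 genes, 471 were higher and 56 lower in untreated shDCLK1 cells, and 238 were higher and 312 lower with LPS, so that much of the smaller rise lay in the level without LPS. LPS lowered 2005 genes as far, with a median interaction of 0.34 (camera p = 9.50e-18, and p = 6.87e-06 with an estimated correlation). Of these 1311 fell less and 120 fell further in shDCLK1 cells. After median-of-ratios scaling the raised and lowered genes were 1210 and 1226, with median interactions of -0.37 and 0.37, so the larger number of falls rests on the scale of the values. In untreated shDCLK1 cells 281 of the 2005 were higher and 790 lower, and with LPS 1230 were higher and 79 lower. Without the interferon list, 778 raised genes had a median interaction of -0.37, with 451 smaller and 106 larger rises.

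Interferon genes rose less in shDCLK1 cells in 46 of 47 members (46 adjusted over the list alone, median interaction -1.43). The list was called at camera adjusted p = 1.08e-46, and at adjusted p = 0.00240 with an estimated correlation. Oasl2 ended at 225 ± 2.52 FPKM in shDCLK1 cells and 222 ± 6.18 in control cells, so that its interaction lay in the level without LPS. Ifit3 had an interaction of -2.49. NF-κB subunits and feedback inhibitors rose less in 16 of 25 and more in 1 (18 adjusted over the list alone, camera adjusted p = 3.51e-08, and adjusted p = 0.00240 with an estimated correlation). The levels without LPS were close for Tnfaip3, at 7.96 ± 0.413 FPKM in shDCLK1 and 7.21 ± 0.201 in control cells, and for Bcl3, at 11.3 ± 0.330 and 10.5 ± 0.505. They were apart for others, with 8 of 25 members higher and 3 lower, among them Cd40 (1.46-fold higher) and Sqstm1 (1.49-fold higher). Nfkbiz had an interaction of -1.17 beside -1.41 for Bcl3 and -1.40 for Tnfaip3. Cytokines had a negative interaction in 14 of 23 and a positive one in 4 (19 adjusted over the list alone, camera adjusted p = 2.63e-05), with -2.37 for Il33, -2.05 for Il6 and -1.66 for Tnfsf9. Chemokines had 10 negative and 6 positive of 18 (16 adjusted over the list alone, camera adjusted p = 0.0176), with -2.37 for Cxcl10 and -2.16 for Ccl4. This call was lost at adjusted p = 0.149 with an estimated correlation, at 0.102 after median-of-ratios scaling, at 0.0920 after quantile normalization and at 0.0552 with no filter on low genes. Inflammatory enzymes had 15 negative and 7 positive of 26 (22 adjusted over the list alone, camera adjusted p = 9.22e-04, and adjusted p = 0.0827 with an estimated correlation), with -1.91 for Acod1 and 2.40 for Mmp9.

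Cell cycle genes fell less in shDCLK1 cells in 39 of 40 (40 adjusted over the list alone, median interaction 1.03). The list was called at camera adjusted p = 5.41e-19, and at adjusted p = 0.00560 with an estimated correlation, with 1.47 for both Cenpf and Ccna2. MHC and antigen presentation genes had 15 negative and 2 positive interactions of 19 (18 adjusted over the list alone, camera adjusted p = 3.48e-08). H2-Aa rose from 13.3 ± 0.703 to 22.5 ± 0.434 FPKM in control cells and fell from 27.4 ± 0.620 to 8.24 ± 0.598 in shDCLK1 cells, and H2-Ab1 had an interaction of -2.25. Stress response genes had 19 negative and 1 positive of 25 (20 adjusted over the list alone, camera adjusted p = 6.82e-09). Atf5 went from 47.2 ± 3.47 to 104 ± 2.69 FPKM in control cells and from 89.1 ± 5.63 to 58.3 ± 3.25 in shDCLK1 cells, and Trib3 had an interaction of -1.62. Immediate-early factors had 17 negative and 6 positive of 29 (23 adjusted over the list alone, camera adjusted p = 2.63e-05), with -1.33 for Atf3 and -1.40 for Gadd45b. Macrophage identity genes had 11 positive and 12 negative of 27 (24 adjusted over the list alone, and adjusted p = 0.0827 with an estimated correlation), with -2.24 for Msr1 and 1.87 for Csf1r. Cholesterol synthesis genes had 2 positive and 10 negative of 23 (12 adjusted over the list alone, and adjusted p = 0.149 with an estimated correlation), with -0.79 for Idi1 and -0.55 for Insig1. Oxidative phosphorylation genes had 19 positive and 0 negative of 31 (19 adjusted over the list alone, and adjusted p = 0.550 with an estimated correlation), with 0.31 for Ndufv1 and 0.29 for Cyc1. Dendritic cell markers had 3 negative and 0 positive of 6 (3 adjusted over the list alone, and adjusted p = 0.107 with an estimated correlation), with -1.03 for Ccr7 and -0.53 for Siglech. Median-of-ratios scaling ended the calls of the macrophage, oxidative phosphorylation and dendritic lists (adjusted p = 0.102, 0.268 and 0.0810). It gave calls for the osteoclast, lysosome and histone lists (adjusted p = 0.0381, 0.0330 and 0.0423).

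The IKK and TLR4 list was not called for the interaction (camera adjusted p = 0.0819) but was after median-of-ratios scaling (adjusted p = 0.0456). It had 6 positive and 10 negative members of 29 (17 adjusted over the list alone), led by Map3k8 (-0.92), Irak3 (-0.86) and Ticam2 (-0.62). Ikbkb had an interaction of 0.14 (adjusted p = 0.0367). It was lost after median-of-ratios scaling (adjusted p = 0.450), quantile normalization (adjusted p = 0.216), rescaling to equal sums (adjusted p = 0.0595) and with weights per library (adjusted p = 0.0651). It was also lost in 7 of the 12 fits without 1 library: untreated control 2 (adjusted p = 0.0885), untreated shDCLK1 1 and 2 (0.0525 and 0.0791), control with LPS 1 and 3 (0.0575 and 0.0869) and shDCLK1 with LPS 1 and 2 (0.0571 and 0.0759).

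The interaction passed the limma threshold for 5464 genes, 3601 positive and 1863 negative, and 191 were at least 1 and 219 at most -1. The split was 2534 positive and 2608 negative after median-of-ratios scaling, which moved the median of all genes from 0.09 to 0.00, and 2710 positive and 2394 negative after quantile normalization. Over the 5 comparisons, in the order given, camera called 13, 16, 15, 17 and 13 of 24 lists, and 9, 10, 6, 5 and 7 of these calls held with an estimated correlation.

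The responses of the lines to LPS were alike in order over the 11052 genes, with Pearson's r = 0.936 and Spearman's rho = 0.914, and a slope of 0.766 for shDCLK1 on control cells. Genes are not independent replicates, and no library is shared between the 2 responses. Rises were called in both lines for 2304 genes (681 for independent lists) and falls for 6151 (4100 for independent lists), and 232 genes were called in opposite directions. The difference between the lines was far less alike without and with LPS, at r = 0.0712 and rho = 0.0285. Of the genes called in both, 1000 were higher each time (810 for independent lists), 416 lower each time (374 for independent lists) and 1377 changed sides. Of the last, 440 were higher without and lower with LPS. A count for independent lists was not computed for genes that changed sides. The excess of genes on the same side is therefore not by itself a sign of agreement, since those that changed sides may exceed such a count too.

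**Figure D3:**
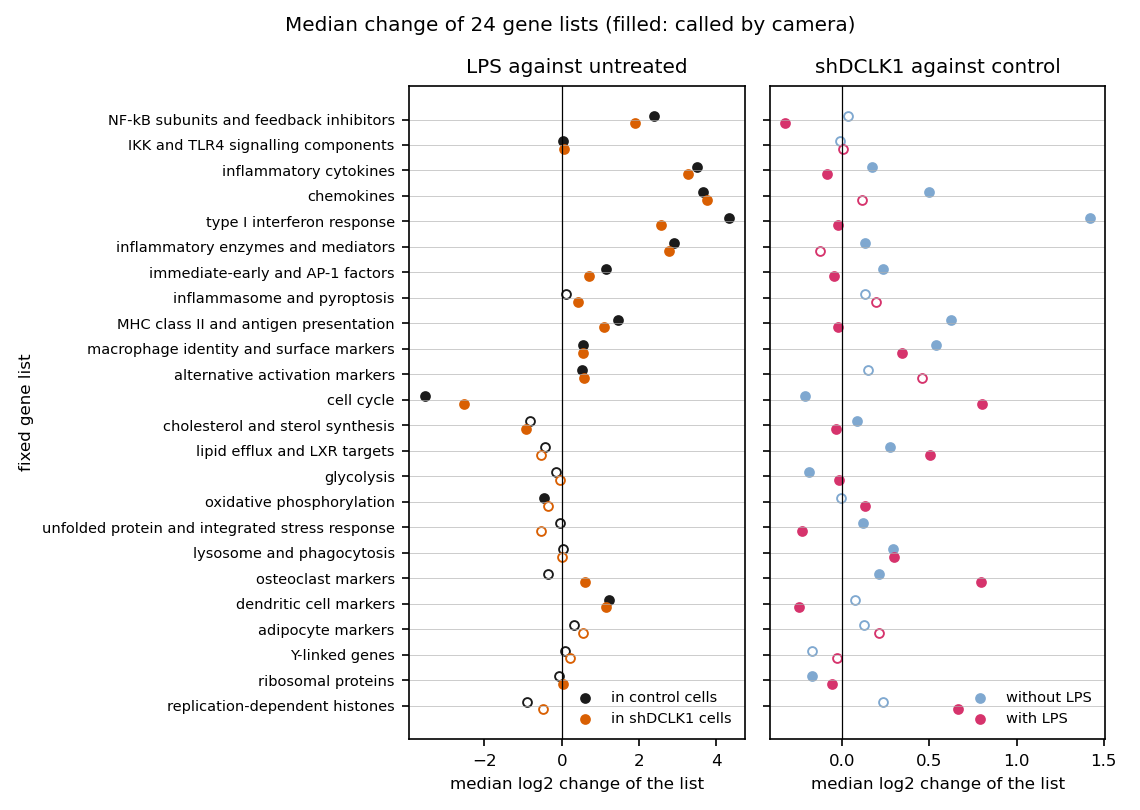
Median log2 change (x axes, log2(FPKM + 1) scale) of 24 fixed gene lists (y axis), with LPS against untreated in each line on the left and shDCLK1 against control cells on the right, filled where camera with a preset correlation called the list. The interferon list lies at 1.42 in shDCLK1 against control cells without LPS and at -0.02 with LPS, and the cell cycle list at -0.21 and 0.80, while after median-of-ratios scaling medians near 0 can change sign, as for ribosomal protein genes in control cells with LPS (from -0.08 to 0.35).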

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

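The counts over other splits of the libraries were planned before the data were examined, while the tests of the 2 patterns weighed here were chosen after the results were seen.

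The lines differed in their response to LPS by a test of the interaction of line and treatment for 5464 genes, 13 gene lists, the LPS-raised genes (median -0.40) and the LPS-lowered genes (median 0.34). The genes named for it were Plau (3.78), Car2 (3.77), Snord42b (3.74), Snord99 (3.44), Id3 (3.15), Ccl2 (3.06), Ms4a6d (-3.05), Oasl2 (-2.94), Ms4a6c (-2.91), Zbp1 (-2.58), Lilrb4a (-2.55) and Ifi44l (-2.55). Of the NF-κB and the IKK and TLR4 lists they were Bcl3 (-1.41), Tnfaip3 (-1.40), Nfkbiz (-1.17), Map3k8 (-0.92), Irak3 (-0.86) and Ticam2 (-0.62). Of the other primary lists they were Il33 (-2.37), Il6 (-2.05), Tnfsf9 (-1.66), Cxcl10 (-2.37), Ccl4 (-2.16), Ifit3 (-2.49), Mmp9 (2.40) and Acod1 (-1.91). A further 17 named genes had a called interaction. Snord42b and Snord99 rest on few fragments: with LPS Snord42b was at 11.3, 0 and 2.79 FPKM in control and 8.4, 2.82 and 2.85 in shDCLK1 cells.

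Of 100 drawn splits of the lines within each treatment, 1, the real one, called as many genes for the interaction (5464). The highest other, 5254, came from the split that swaps the lines in the LPS libraries alone, which sums the differences between the lines in place of subtracting them, and the next called 2127. Likewise 1 of 100 gave as large a median for the LPS-raised genes (-0.40, highest other 0.32 in size) and 1 of 100 for the LPS-lowered genes (0.34, highest other 0.27 in size). A chance division of these libraries into lines is therefore excluded for all 3. Such splits also break up the difference between the lines within each treatment, so they do not test the interaction by itself. For the other comparisons the 10 splits of 6 libraries are too few for a share under 0.05. In each, 1 split, the real one, called as many genes: 9604 for LPS in control cells (highest other 1), 9349 in shDCLK1 cells (highest other 0), 4976 between the lines without LPS (highest other 1) and 5371 with LPS (highest other 0).

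Interferon response genes were higher in untreated shDCLK1 cells, and their smaller rise with LPS rests largely on that start. RNA of LPS-treated cells in those libraries would have to make up 11.9% of them at the median interferon gene, but 8 near-silent cytokine and chemokine genes show a share of at most 1.01% (Cxcl11), which argues against it. Scaling does not account for it either, since the lowest median over 3 other scalings was 1.42, against 1.42 as deposited. A response to the knockdown and a difference between the 2 clonal lines that has nothing to do with it cannot be told apart, because each arm is 1 line and Dclk1 was at most 0.01 FPKM in control cells.

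Cell cycle genes fell less with LPS in shDCLK1 cells. A lower start in those cells is excluded as the whole cause, as 38 of 40 genes were higher with LPS. Part of the difference lay in the level without LPS, where the list's median against control cells was -0.21, beside 0.80 with LPS. The pseudocount is excluded, since the median interaction was 1.18 with 0.1 in place of 1 (1.03). Cells that did not respond to LPS would need a median share of 8.24% in the shDCLK1 cultures. The first test of this found 1 abundant gene outside the list (Cd24a, kept at 0.964% of its untreated level) under 0.5 times that share, so such cells stay open as part of the cause, beside a weaker arrest. A second test, set after the first was seen, is left out here and not used. As the whole cause, 1 share would have to hold for all genes, with responding cells falling as control cells did. The ranges of the shares over libraries lay apart for some genes, with 1.27% to 2.96% for Tk1, 13.4% to 17.4% for Mcm4 and 51.2% to 69.2% for Ccnd1. In a later test, set with shares in view, at most 19 of 40 genes held the same share. Its bound, 20 or fewer, was barely met, but ranges this far apart argue against such cells as the whole cause.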

How the results depend on the processing

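The fit without the untreated libraries numbered 3 was added after the data were seen, and the other alternatives were planned.

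Of 182 values for the 8 main results (the 5 counts of called genes, the interactions over LPS-raised and LPS-lowered genes and the agreement of the differences between lines), 174 stayed within the bounds set, and 8 values of the agreement moved. The bounds were a factor of 1.5 for counts, the same direction and call for medians, and 0.00594 for the agreement, the SD of its r over the 12 fits without 1 library. The bound for counts is wide and ignores direction. It passed 3823 for 4976 genes without LPS, and a split with LPS that turned from 3788 up and 1583 down to 2573 up and 2891 down after median-of-ratios scaling. Its r over genes was 0.0712 as reported. It was 0.0508 with a pseudocount of 0.1, 0.0617 with the filter at 5 FPKM, 0.0647 after median-of-ratios scaling, 0.0652 after rescaling to equal sums and 0.0939 after quantile normalization. Without 1 library it ranged from 0.0584 to 0.0827. It stayed near 0 throughout, and the cause of these moves was not tested.

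Of 5102 values for 224 results of named genes, 5076 kept their direction and side of the threshold, 22 lost their call and 4 changed direction. The last were Ikbkb with LPS after median-of-ratios scaling, at 0.0631 in control and 0.112 in shDCLK1 cells, Ikbkb in shDCLK1 cells after quantile normalization, at 0.0645, and Rplp1 in shDCLK1 cells after quantile normalization, at -0.56. Scaling removes the shift of the median of all genes with LPS (-0.38 in control and -0.29 in shDCLK1 cells), which is as large as the change of Ikbkb. The cause for Rplp1 was not tested. Most named genes were picked from these same data as called genes with the largest changes, so most were near certain to keep their call. The share kept does not carry over to called genes in general. Of 690 values for 30 results of the primary lists, 670 kept their side, 14 lost the call and 6 gained one, and camera gave none with a call the other direction. Medians near 0 did change sign, as for the IKK and TLR4 list with LPS, from 0.00345 to -0.0749 after median-of-ratios scaling.

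With 1 library left out, the counts of called genes ranged from 9411 to 9629 for LPS in control cells, 9148 to 9352 in shDCLK1 cells, 4360.0 to 5102 between the lines without LPS, 4697 to 5400.0 with LPS and 5067 to 5349 for the interaction. The medians ranged from -0.42 to -0.39 for raised and from 0.34 to 0.35 for lowered genes. Without the untreated libraries numbered 3 the counts were 9402, 9122, 3823, 5185 and 4745.

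No pairing of the libraries by replicate number was seen over the tested genes, which does not exclude it. Deviations from the group means of the 18 pairs with the same number correlated at r of -0.107 to 0.0638 (median -0.0185), none over 0.1, and 2 of 12 libraries correlated best with their own number. With the number as a replicate block, 9574, 9316, 4804, 5183 and 5296 genes were called, the medians were -0.40 and 0.34, and the agreement was 0.0712. The block changed the call of 1 named gene or primary list, inflammatory enzymes with LPS (adjusted p = 0.0449 in place of 0.0713).

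Depth limits what can be said of Dclk1, at the smallest step of the file, and of short RNA genes such as Snord42b, where 1 fragment is worth 2.83 FPKM. The relative depth of the libraries ran from 0.974 to 1.01, but the genes used for it were chosen in a way that favours equal depths. A shallower group is therefore not excluded.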

Other observations

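The test reported here was chosen after the values were seen.

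The genes that stood at least 1 log2 unit above control cells in shDCLK1 cells both without and with LPS were 20, named here after their values were seen. Lyz2 (2.71 and 2.22) and its copy Lyz1 (2.55 and 2.20) led. Among the others were the sialic acid receptor Siglec1 (2.03 and 2.20), Tm4sf19 (1.95 and 1.77) and the lectin Clec7a (1.64 and 1.98). Spp1 (osteopontin) was among the most abundant, at 602 against 269 FPKM untreated and 1481 against 653 with LPS. No gene was lower by as much in both. Only 21 genes without LPS and 46 with LPS were that far lower, beside 186 and 153 higher, so few shared ones could arise. H2-Ea-ps, Dmwd, Car2 and Ccl5 were past 1 log2 unit in opposite directions.

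The third untreated control library held traces of LPS-raised genes. In untreated shDCLK1 cells library 3 was also the highest for Il1b (0.83, 0.81 and 1.53 FPKM in libraries 1, 2 and 3). The same held for Ccl5 (9.41, 9.16 and 11.75) but not for Il6 (0.25, 0.35 and 0.29). The test below was run on control cells alone. RNA of LPS-treated cells in the third untreated control library would raise each gene in proportion to its level with LPS. Over 34 genes near silent in the other 2 libraries the excess and the LPS level correlated with Spearman's rho = 0.554 (two-sided permutation p = 0.00103, over genes, which are not independent replicates) and Pearson's r = 0.628, and 24 genes lay above the mean of the other 2. The rank correlation lies between the bounds set for and against, 0.8 and 0.5, so such RNA and a weak response of that culture cannot be told apart. The median share would be 0.0565% (quartiles 0 and 0.108).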
